A study of Danio rerio with 7 samples.

How the data were processed

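Brain RNA of 12-month-old male zebrafish of the AB strain was measured on 7 one-colour Agilent arrays of 180880 spots. Per the labels, embryos had been kept in water with 0 or 10 ppb lead, added as lead acetate, from under 2 hours to 72 hours after fertilization, and were then raised without lead. The control group held 4 samples and the exposed group 3. Groups and replicate numbers were taken from the sample labels. Replicates are separate samples in the labels, and nothing in the labels says how many fish stand behind a sample, so p-values measure the spread between these samples, which may be partly technical. The series text also speaks of females, which were not analysed here.

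The deposited scanner files give each spot as a fluorescence intensity on a linear scale. Per the labels' protocols, Cy3 was built into cRNA with Agilent's Low Input Quick Amp kit. Per the submitters' processing notes, images were quantified with Agilent Feature Extraction 11.5, and per the file headers the version was 11.5.1.1, with the protocol GE1_1105_Oct12. The processed signal of those files is background-subtracted and spatially detrended within an array, per the file headers, and is not scaled between arrays. The authors' deposited table of altered probes gives a log2 ratio, a signed fold change and a p-value for each of 1863 probes. The sources used here give neither its test, its normalization, its adjustment for multiple testing nor the direction of its ratio. Every listed p-value of the authors' deposited table was at most 0.05 and every listed fold at least 1.5 in either direction.

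From these files, log2 of the processed signal was taken and the array's 75th percentile over the 176026 non-control spots was subtracted. The 4854 control spots were left out, as were spots marked as outliers by the scanner software. Saturated spots would have been kept, and there were 0. Spots of one probe were averaged. A probe was kept when at least 0.5 of its spots were well above background on at least 3 of the 7 arrays, which left 94881 of 128291 probes. The number of arrays limits the precision of every value.

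Probes carry the accessions of the array's design. Of 42900 probes named by an NCBI transcript, 39952 were matched to 13547 gene symbols through a RefSeq gene table of the assembly GRCz12tu, without versions. The remaining 88339 probes had no symbol here, many of them Ensembl transcripts or expressed sequence tags. The genome build behind the array is not given in the sources used here, so the table served for names only and no coordinates are printed. Of the kept probes, 35958 had a symbol, for 12685 genes.

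Exposed and control samples were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the packages jsonlite 2.0.0 and data.table (1.17.8) for reading. All p-values are two-sided, and an adjusted p is Benjamini-Hochberg adjusted over all kept probes, with a threshold of 0.05. A looser threshold of an unadjusted p under 0.05 with a change of at least 1.5-fold is given as a count only. Differences are exposed minus control on the log2 scale with the standard error (SE) of the fit, from 4 control and 3 exposed samples unless stated. Where a probe was not well above background on any array of a group, its fold was computed with a floor under the dimmer group and is not an exact size. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

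The slide of each array was read from its file. Slide 1 held control replicates 1 and 2 and exposed replicate 1. Slide 2 held control replicates 3 and 4 and exposed replicates 2 and 3. Each result was therefore also computed with slide as a block and within each slide. The position on a slide followed the group: controls lay in positions 1 and 3 and exposed samples in positions 2 and 4, so position and group cannot be told apart within a slide, and position entered as a random block.

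The comparison, its samples, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover the themes of the study (Alzheimer disease, neuronal and transmitter genes, heme synthesis, oxidative and metal response), other cell types that a brain dissection may hold, and genes that move with sampling. They held 1637 members, of which 1202 were measured. Each gene was represented by 1 probe, the one with the highest mean signal. Lists were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry, each adjusted over the 31 lists. The mean of a list per array was compared between groups with an exact two-sided permutation test over the 35 splits of the samples, whose smallest possible p is 0.0286. Another 6 lists were written after the split between slides was seen, and 1 list of glucocorticoid-responsive genes after the genes of smallest p were seen.

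Named genes needed a symbol. Genes past the adjusted threshold came first, up to 12 per direction. Where fewer passed, places were filled by the genes of smallest p among those with an unadjusted p under 0.05, a change of at least 1.5-fold and no overlap between the groups, each by its probe of smallest p. Further named genes were the 6 highest and 6 lowest folds in the authors' deposited table. From each called list, and from the Alzheimer, heme synthesis and oxidative lists in any case, members past the adjusted threshold or otherwise up to 4 of smallest p were named. Alad, hmox1a, mt2, appa, appb, mapta, maptb, apoea, apoeb and gfap were looked up whatever their values. For list members and looked-up genes a gene is its brightest probe. For the folds of the authors' deposited table it is the probe of the largest listed fold, in place of the brightest probe that had been planned.

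The fit was tested on simulated arrays with the spread of the real ones, 93206 probes and 50 changed probes at each size. Without a block it recovered 0 of 50 probes changed 1.5-fold, 0 changed 2-fold, 18 changed 4-fold and 33 changed 8-fold. With slide as a block it recovered 0, 1, 30 and 47. Of 93006 unchanged probes, 0 passed the adjusted threshold without a block and 6 with slide as a block. The looser threshold was passed by 3701 and 2843 of them. Probes were drawn independently of each other, and no slide difference was put into the arrays simulated without a block. The simulated counts are therefore only a rough guide to the real arrays. In 20 simulated comparisons of 12676 genes drawn independently of each other, a list of 40 genes shifted by 0.5 on the log2 scale was called in 20, and 0 of 600 unshifted lists were. Genes of the real lists were correlated, with an estimate of 0.57 for ribosomal proteins and 0.81 for microglia markers. The simulation therefore does not show how often unshifted lists are called in these data.

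The alternatives were quantile normalization, median centring, another background correction, 2 other filters on dim probes, slide, position or replicate number as a block, each slide alone, each sample left out in turn, an intensity trend with a robust prior, unmoderated p-values, array weights, and other ways of handling a gene's probes. The files read here hold no mean spot signal, so normexp was run on median spot and background signals with an offset of 50 in place of the mean signals that had been planned. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.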

Results

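Gene expression was measured in the brains of male zebrafish at 12 months of age, after a short embryonic exposure to lead, a metal toxic to the developing nervous system. The AB fish had lived in clean water since 72 hours after fertilization. There were 4 control samples (0 ppb) and 3 exposed samples (10 ppb), each on its own array. Between 70.5% and 76.1% of the spots of an array were well above background, and the 75th percentile of the processed signal lay between 465 and 938 intensity units. The first principal component held 48.9% of the variance and separated the arrays of slide 1 from those of slide 2. Correlations across probes were 0.965 to 0.977 between arrays of one slide and 0.920 to 0.958 between slides, whether or not the arrays shared a group.

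The comparison of 10 with 0 ppb asks which genes differ in the ageing male brain long after lead exposure of the embryo, with the nervous system and Alzheimer disease as the study's themes. The genes that separated the groups most clearly included hif1al, a hypoxia-inducible factor, whose signal was 2.16-fold higher in exposed samples (log2 difference 1.11, SE 0.19), and pfkfb4b, an enzyme that sets the rate of glycolysis, which was 2.17-fold higher (1.12, SE 0.24). The neuropeptide gene urp2 was 4.26-fold lower (-2.09, SE 0.48), and the transcription factor genes olig3, atoh1b and gbx2, which pattern the neural tube, were 2.17-fold, 2.16-fold and 1.81-fold lower. As lists, red blood cell markers, immediate early genes and ribosomal proteins were higher in exposed samples when genes were treated as nearly independent. Hypothalamic neuropeptides were lower. In 34 of the 35 splits of the samples at least as many lists were called that way, and 0 lists passed with an estimated correlation. None of the genes named above passed the adjusted threshold. These directions are those of the sample labels, and they are opposite in sign to the ratios in the authors' deposited table.

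Of 94881 probes, 0 had an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.755. At an unadjusted p under 0.05 there were 2216 probes (2.34%), against 4744 expected by chance, and 3020 with unmoderated p-values. At the looser threshold there were 1634 probes, 1046 higher and 588 lower in exposed samples. The share that was higher depended on the scaling: 64.0% as given, 49.4% with quantile normalization (772 higher, 792 lower) and 51.7% with median centring (816 higher, 761 lower). With slide as a block 0 probes passed the adjusted threshold (smallest adjusted p 0.116), and 3705 had an unadjusted p under 0.05. The groups did not overlap for 3681 probes (3.88%), against 5.71% by chance. In the simulated test of this comparison, 18 of 50 probes changed 4-fold were recovered and 0 of 50 changed 2-fold.

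Of 12503 named genes on the array, 203 met the criteria of unadjusted p, size and separation. By at least 1 probe, 108 met them as higher and 99 as lower, so some genes did so in both directions. This count was not taken over the other splits of the samples. The 12 of smallest p in each direction are described here by value. The probe of smallest p on the array has no gene name here. It was 11.8-fold higher in exposed samples (log2 difference 3.56, SE 0.32), by 3.51 within slide 1 and 3.40 within slide 2, and it is named here after its values were seen.

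Among the 12 genes that were higher in exposed samples, for hif1al all 10 probes were higher and 8 had an unadjusted p under 0.05, and for pfkfb4b all 3 probes were higher. The vitamin B12 trafficking gene mmadhca was 2.19-fold higher (log2 difference 1.13, SE 0.21) and plin2, which coats lipid droplets, 2.02-fold higher (1.01, SE 0.21). The complexin gene cplx3a, a regulator of vesicle fusion, was 2.84-fold higher (1.51, SE 0.32), the calcium channel subunit cacna2d1a 1.86-fold higher (0.90, SE 0.17) and the neuropeptide gene npffl 2.05-fold higher (1.03, SE 0.19), with its other probe lower and 2 of 4 control arrays well above background. The actin regulator ssh2b (0.99, SE 0.19), the RNA-binding gene ewsr1b (1.11, SE 0.21), the kinase activator mob2a (1.06, SE 0.23) and fam107b (0.99, SE 0.18) were higher by 5 of 5, 6 of 7, 6 of 6 and 4 of 4 probes. The homeobox gene hnf1bb (1.67, SE 0.35, 3 controls) was well above background on 1 of 4 control arrays, and 2 of its 3 probes were lower.

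Among the 12 genes that were lower in exposed samples, the muscle calcium-store protein casq2 was 3.61-fold lower (log2 difference -1.85, SE 0.46; 4 of 4 probes) and the epithelial keratin krt5 3.42-fold lower (-1.77, SE 0.43), with 13 of 13 probes lower but 1 at an unadjusted p under 0.05. The carboxypeptidase gene cpa5, also a member of the list of neutrophil markers used below, was 2.70-fold lower (-1.43, SE 0.24). Among the transcription factor genes, olig3 differed by -1.12 (SE 0.18), with its other probe higher, atoh1b by -1.11 (SE 0.23; well above background on 2 of 3 exposed arrays) and gbx2 by -0.85 (SE 0.20). The ectonucleotidase entpd2a.1 (-1.03, SE 0.19), the secreted synaptic protein lgi2a (-1.02, SE 0.23), tgds (-0.87, SE 0.17, with 5 of 8 probes lower), the cholesterol synthesis enzyme ebp (-0.83, SE 0.20) and the G-protein regulator rgs3a (-0.71, SE 0.17) were lower as well. These 24 genes were chosen for groups that do not overlap, which fixes their sign within each slide and with slide as a block but not the size of the difference. For urp2 the difference was -2.45 within slide 1 and -1.59 within slide 2, and for krt5 -2.90 and -0.93. None of these 24 genes passed the adjusted threshold, and the adjusted p of each in limma was 1.00.

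**Figure D1:**
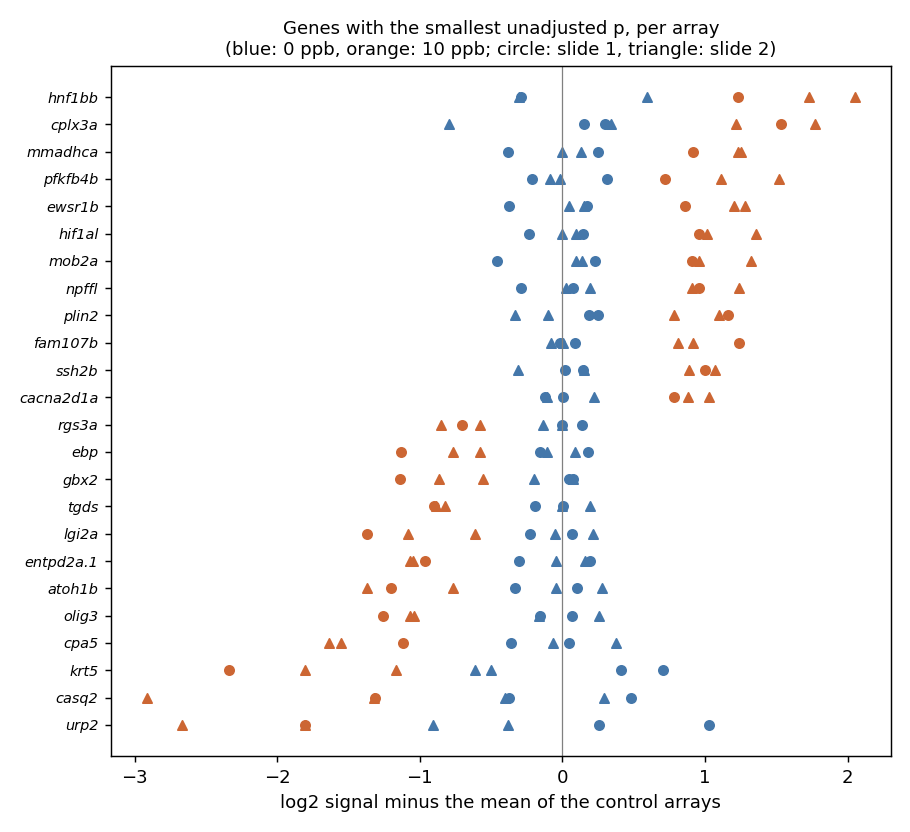
Log2 signal of the 24 named genes of smallest unadjusted p on each array, relative to the mean of the control arrays (x axis, log2), with 1 gene per line. Blue marks 0 ppb, orange 10 ppb, circles slide 1 and triangles slide 2; the groups do not overlap for any of these genes, which were chosen for that, and urp2 is the lowest at -2.09 on average.

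Of 31 gene lists, 4 passed the adjusted threshold with a preset correlation of 0.01, and 0 passed with an estimated correlation (smallest adjusted p = 0.997) or with fry (smallest adjusted p = 0.995). The estimated correlation also passed 0 lists between slides, where 24 of 31 microglia genes passed singly, so its result cannot show that a list is unchanged. The preset correlation called at least 4 lists in 34 of the 35 splits of the samples, so its calls do not set exposure apart. In each of the 4 lists, 0 members passed the adjusted threshold over all probes and 0 when adjusted over the list alone. The same 4 lists passed with slide as a block, together with the interferon list (adjusted p = 0.0247), and 0 did so there with an estimated correlation.

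Red blood cell markers, which a brain dissection carries in its vessels, lay higher as a list: 18 of 21 were higher and 3 lower. The median log2 difference was 0.42 (camera adjusted p = 1.27e-05 with the preset correlation, 0.997 with an estimated correlation). The adult globin genes hbaa2 (1.03, SE 0.52) and hbba2 (0.97, SE 0.41), alas2, the red-cell enzyme that starts heme synthesis (0.98, SE 0.32), and the anion exchanger slc4a1a (0.69, SE 0.31) had the smallest p. The median was 0.44 within slide 1, where the list was not called (adjusted p = 0.278), and 0.61 within slide 2. Control replicate 1 had a list mean of 0.49, above the exposed samples (0.16 to 0.27), and the exact permutation p of the list mean was 0.171.

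Hypothalamic neuropeptides and their receptors lay lower as a list: 33 of 45 were lower and 12 higher. The median was -0.26 (camera adjusted p = 5.80e-04 with the preset correlation, 0.997 with an estimated correlation). Beside urp2, the members of smallest p were kiss2, a peptide of the reproductive axis (-0.61, SE 0.27), vip, the vasoactive intestinal peptide (-0.58, SE 0.22), and nucb2b, the precursor of the feeding peptide nesfatin (-0.46, SE 0.18). The median was -0.08 within slide 1, where the list was not called, and -0.27 within slide 2. It was also not called without exposed replicate 2 (adjusted p = 0.203), whose list mean was -0.49, when the median was -0.11, and it was -0.40 without exposed replicate 3. In exposed replicate 2 the list means of ependyma (-0.69), radial glia (-0.66), liver (-0.55), retina (-0.47) and neurogenesis genes (-0.34) were likewise the lowest of the 7 arrays. The exact permutation p of the list mean was 0.0571.

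Immediate early genes, which neurons switch on within minutes of activity, lay higher as a list: 35 of 48 were higher and 13 lower. The median was 0.16 (camera adjusted p = 1.17e-04 with the preset correlation, 0.997 with an estimated correlation). The leading members were klf9, a transcription factor gene that answers glucocorticoid and thyroid hormone (2.04, SE 0.63), the phosphatase dusp2 (2.14-fold, log2 SE 0.35), and the transcription factors egr2b (0.60, SE 0.24) and junba (0.51, SE 0.24). The median was 0.24 within slide 1 and 0.16 within slide 2, and the exact permutation p was 0.171. Without exposed replicate 2 the list was not called (adjusted p = 0.116) though its median was 0.22, and without exposed replicate 1 the median was 0.32.

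Cytosolic ribosomal proteins lay higher as a list by a small amount: 79 of 81 were higher and 2 lower. The median was 0.17 (camera adjusted p = 2.29e-15 with the preset correlation, 0.997 with an estimated correlation). The members of smallest p were rpl26 (0.41, SE 0.23), rpl23 (0.29, SE 0.18), rpl24 (0.28, SE 0.17) and rps19 (0.26, SE 0.16). The list mean of exposed replicate 2 (-0.13) lay below all 4 controls, and the exact permutation p was 0.2. The median was 0.33 within slide 1 and 0.09 within slide 2, 0.10 without exposed replicate 1 and 0.30 without exposed replicate 2. The medians of the 4 lists kept their direction under quantile normalization (0.38 for red blood cell markers, -0.25 for neuropeptides, 0.18 for immediate early genes and 0.10 for ribosomal proteins), median centring and normexp.

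**Figure D2:**
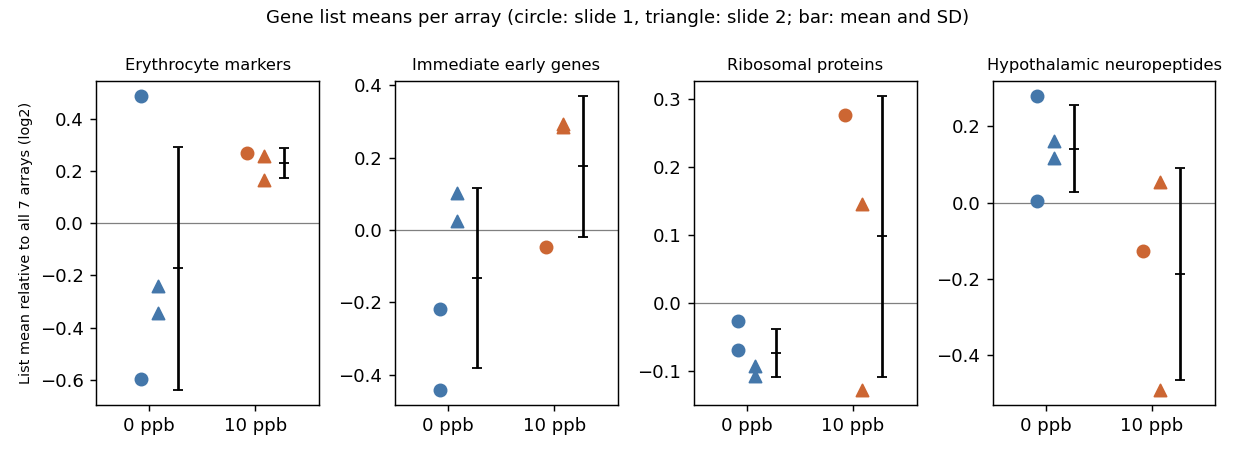
Mean log2 signal of 4 gene lists on each array, relative to the mean of all 7 arrays (y axis, log2), for 0 and 10 ppb. Circles are slide 1, triangles slide 2 and bars the mean with its SD; the groups overlap in each panel, as for red blood cell markers, where control replicate 1 stands at 0.49.

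The genes of the study's own themes differed little. Of 43 measured Alzheimer disease genes 17 were higher and 26 lower (median log2 difference -0.05, adjusted p = 0.997), and 0 passed the adjusted threshold, over all probes or adjusted over the list alone. The amyloid precursor genes appa (0.07, SE 0.27) and appb (-0.05, SE 0.16) and the apolipoprotein gene apoeb (0.11, SE 0.57) were within their error. The endocytic adaptors picalma (0.30, SE 0.23) and picalmb (-0.24, SE 0.18), fermt2 (0.30, SE 0.17) and the gamma-secretase subunit aph1b (-0.26, SE 0.21) had the smallest p. The other apolipoprotein E gene, apoea, was not kept, and mapta and maptb, the tau genes, had no probe under those symbols. The slides went opposite ways for apoeb (1.37 within slide 1, -0.39 within slide 2), appa (-0.39 and 0.29), picalma (-0.01 and 0.41) and aph1b (0.09 and -0.40).

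Genes of the known targets of lead did not pass as lists. Of 10 heme synthesis genes 5 were higher and 5 lower (median -0.02, adjusted p = 0.786). Alad, the heme enzyme that lead inhibits, differed by -0.05 (SE 0.24), hmbsb by -0.15 (SE 0.19), hmbsa by -0.30 (SE 0.30) and cpox by -0.33 (SE 0.35). The member of smallest p was alas2, which is also a red blood cell marker (0.98, SE 0.32, unadjusted p = 0.0170, 6 of 6 probes higher). Of 38 antioxidant and metal response genes 10 were higher and 28 lower (median -0.11, adjusted p = 0.0783), and the list was called in 5 of 24 settings. Among them were the metallothionein mt2 (-0.61, SE 0.33, with 4 of 4 probes lower, 2 of them at an unadjusted p under 0.05), the heme oxygenases hmox2a (-0.44, SE 0.19, unadjusted p = 0.0506, 3 of 3 probes lower) and hmox1a (-0.64, SE 0.90), nqo1 (-0.38, SE 0.23) and the metal transporter slc11a2 (-0.25, SE 0.15). The astroglial gene gfap differed by -0.15 (SE 0.65). The slides went opposite ways for gfap (0.89 within slide 1, -0.40 within slide 2) and hmox1a (0.56 and -0.87). In the heme and the oxidative list 0 members passed the adjusted threshold, over all probes or adjusted over the list alone.

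Lists of neurons and signalling did not pass over all 7 arrays. Of 19 neuronal markers 7 were higher (median -0.01, adjusted p = 0.893), of 35 synaptic vesicle genes 16 (-0.01, 0.786), of 23 glutamate genes 15 (0.04, 0.709), of 21 GABA and glycine genes 12 (0.05, 0.786) and of 46 monoamine and acetylcholine genes 25 (0.03, 0.788). Of 51 calcium, kinase and neurotrophin genes 30 were higher (0.04, 0.786), of 54 axon guidance genes 33 (0.05, 0.234), of 68 neurogenesis genes 23 (-0.08, 0.805), of 44 clock genes 20 (-0.01, 0.940) and of 40 epigenetic regulators 16 (-0.02, 0.997). Heat shock genes (25 of 52 higher, -0.00, 0.805) and oxidative phosphorylation genes (21 of 79 higher, -0.07, 0.0783) did not pass either, though the latter list was called in 8 of 24 settings, among them quantile normalization, median centring and normexp. Within slides some were called in opposite directions, GABA and glycine genes lower in slide 1 (-0.26) and higher in slide 2 (0.23) and neurogenesis genes higher in slide 1 (0.19) and lower in slide 2 (-0.18). Neuronal (-0.27) and monoamine and acetylcholine genes (-0.23) were called lower within slide 1 and axon guidance genes (0.10) higher within slide 2. Without exposed replicate 1 the neuronal, synaptic vesicle, glutamate, GABA, monoamine, calcium and axon guidance lists were each called higher. Every fit without that sample sets exposed samples of slide 2 alone against controls of both slides, so it mixes slide with exposure. All of these lists but GABA passed as lower on slide 1 between slides (camera adjusted p at most 0.0271 with the preset correlation). In these lists 0 members passed, over all probes or adjusted over the list alone.

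Markers of other cell types did not pass either. Oligodendrocyte markers had 6 of 18 higher (median -0.06, adjusted p = 0.234), radial glia 7 of 22 (-0.10, 0.400), ependyma and choroid plexus 8 of 31 (-0.18, 0.224), endothelium 12 of 30 (-0.10, 0.786) and meninges, skin and bone 8 of 38 (-0.25, 0.0783); the ependyma and meninges lists were called lower in 2 and 4 of 24 settings. Muscle markers had 11 of 39 higher (-0.17, 0.800), with 1 control, replicate 2, at a list mean of 1.38; the list was called lower within slide 1 (-0.66), higher within slide 2 (0.40) and higher without control replicate 2 (0.17). Pituitary markers had 8 of 16 higher (-0.01, 0.788), retina and pineal markers 19 of 42 (-0.04, 0.893), liver genes 10 of 25 (-0.19, 0.885) and gonad genes 20 of 37 (0.03, 0.903). Microglia and macrophage markers had 3 of 31 higher (-0.68, 0.0609), and their median was 0.89 within slide 1 and -0.97 within slide 2. The microglia list was called in 9 of 24 settings, higher within slide 1 and lower in the others, and its median was -1.93 without exposed replicate 1 (adjusted p = 1.43e-10), -0.13 without exposed replicate 2, -0.08 without exposed replicate 3 and -0.22 without control replicate 2. Interferon and inflammation genes had 21 of 55 higher (-0.20, 0.966), and their median was 0.75 within slide 1, -0.19 within slide 2 and 0.13 with slide as a block, and they were called in 5 of 24 settings. The signs of median, mean and test differed among themselves in 9 lists, those of epigenetic regulators, gonad, heat shock, interferon, heme, liver, neuronal, retina and synaptic vesicle genes. In these lists too 0 members passed, over all probes or adjusted over the list alone.

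The authors' deposited table lists 1863 probes, 545 with a positive and 1318 with a negative ratio. All 1863 had the opposite sign here for 10 minus 0 ppb, with a correlation across probes of -0.989. Of these probes 893 (47.9%) did not pass the filter on dim probes, and 607 were not well above background on any array. Of the 970 kept probes 965 had an unadjusted p under 0.05 here and 0 passed the adjusted threshold. The table was chosen on these same samples, so it is no independent evidence for any gene in it.

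The largest folds of the authors' deposited table were of this kind. Its ratio for klf9 was -2.193, and here that gene was 4.63-fold higher in exposed samples (log2 difference 2.21, SE 0.64), by 3 of 3 probes. The lipid-binding gene osbpl3a (1.80, SE 0.46) and the claudin cldng (1.62, SE 0.44) were higher, though well above background on 1 and 2 of the 4 control arrays. The complement gene c3a.6, the muscle myosin smyhc2 and trim55a were 3.95-fold, 3.72-fold and 3.09-fold higher. Each was well above background on 0 of 4 control and 1 of 3 exposed arrays and so was not tested. The 1 kept probe of trim55a was lower. Lower were the acetylcholine receptor subunit chrna1 (-2.11, SE 0.53) and the photoreceptor gene rcvrn3 (-1.81, SE 0.46, with its other probe higher), each well above background on 1 of 3 exposed arrays. The claudin cldne was 4.69-fold lower and well above background on 3 of 4 control and 0 of 3 exposed arrays (limma adjusted p = 1.00). The floor left the folds of smyhc2, trim55a and cldne unchanged, so these are plain ratios that include dim signals and not lower limits. The highest ratio in the authors' deposited table was 5.39 for the heat shock gene hspa1b. Outlier marks left 1 control value of that probe here, and the difference was -0.68 (SE 0.88).

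The 2 slides differed for more probes than the 2 groups did, most clearly for immune genes. On slide 1 the microglia and macrophage markers were higher for 31 of 31 genes, by a median of 2.71 on the log2 scale or 6.52-fold. The difference was 2.02 among controls and 3.71 among exposed samples (adjusted p = 1.93e-17 with the preset correlation, 0.533 with an estimated correlation). Interferon and inflammation genes were higher for 48 of 55 genes, by a median of 1.47 (adjusted p = 0.533 with an estimated correlation). With the group as a block, 24 of the 31 microglia genes and 31 of the 55 interferon genes passed the adjusted threshold over all probes, each higher on slide 1. They included c1qc, a complement gene of microglia (3.77, SE 0.43, adjusted p = 0.0118), mpeg1.1 of macrophages (3.16, SE 0.60, 0.0307), the cytokine genes tnfa (3.32, SE 0.30, 0.00853) and ifng1, the interferon gamma gene (6.52, SE 0.61, 0.00875), and the antiviral gene mxe (5.69, SE 0.42, 0.00623), which were picked after their values were seen. On slide 2 the signal of ifng1 was low, at -7.16 to -5.51 on the log2 scale, so the size of its difference is uncertain.

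Over all probes 8402 of 94667 (8.88%) passed in limma between slides, 3669 higher and 4733 lower on slide 1. With the preset correlation 15 of 31 lists passed, among them muscle (median 0.64 on slide 1 over slide 2), meninges (0.74) and glutamate signalling (-0.44), and also immediate early genes (-0.32, with 11 of 48 members past the adjusted threshold) and ribosomal proteins (0.09), which were called by exposure as well; 0 passed with an estimated correlation. For muscle markers control replicate 2 set the value: the median slide difference was 1.01 among controls and -0.21 among exposed samples. Clock genes did not pass as a list between slides (camera adjusted p = 0.818 with the preset correlation). Of their 44 members, however, 10 passed the adjusted threshold, 5 higher and 5 lower on slide 1. Of the 1000 probes of smallest p between slides among controls alone, 920 had the same sign among exposed samples, with a correlation across probes of 0.740.

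**Figure D3:**
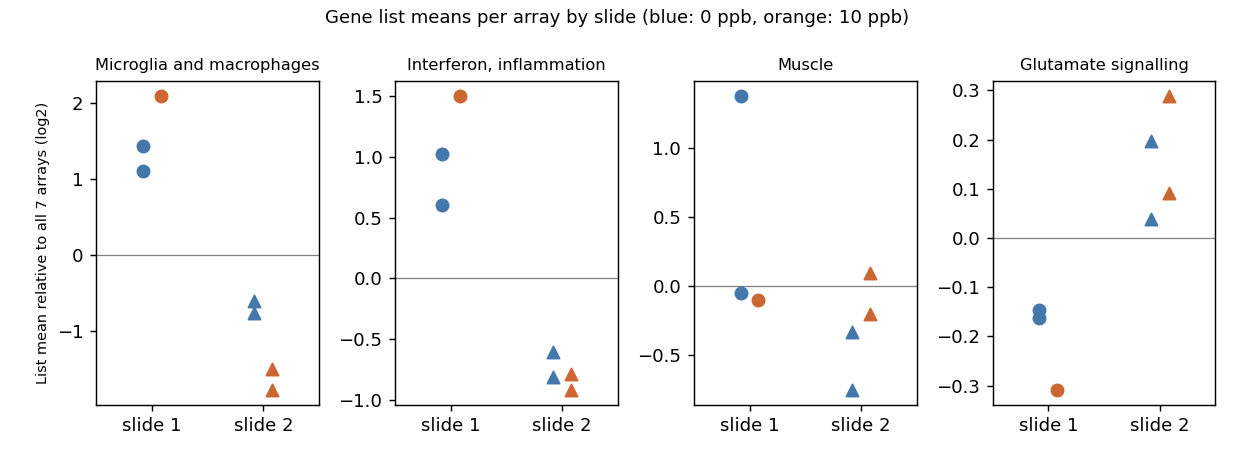
Mean log2 signal of 4 gene lists on each array, relative to the mean of all 7 arrays (y axis, log2), for slide 1 and slide 2, with 0 ppb in blue and 10 ppb in orange. Microglia and interferon lists are higher on slide 1 in both groups, with a median difference of 2.71 for microglia; for muscle markers control replicate 2 stands apart at 1.38.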

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

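Of 95 values tested for a control sample standing apart from the other 3 (64 probes of named genes and 31 lists), 5 did so, and chance gives 4.75. Groups of 3 were not tested. The tests of the split between slides were chosen after that split was seen, except the test on spike-in probes, which was set out before its result was known.

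Control replicate 4 was the lowest control for cplx3a, at -5.56 on the log2 scale against -4.61 to -4.42 in the others, and for rpl26, at 7.14 against 7.71 to 7.81. Control replicate 3 was the lowest for gbx2, at -0.19 against 0.05 to 0.08. Control replicate 2 was the lowest for picalma, at 3.56 against 3.90 to 3.95, and for the mean of the pituitary list, at -0.34 against 0.11 to 0.16.

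The higher level of microglia, macrophage and interferon genes on slide 1 is the clearest pattern between samples, and it lies across both groups. Hybridisation or scanning of the slide as a whole is argued against as the cause: the 6 spike-in probes above background differed by a median of -0.36 between slides (range -0.42 to -0.30), and 0 of 10000 lists of like brightness reached the 2.71 of the microglia list (highest 0.37). The arrays of slide 1 did carry more spots marked as outliers, 2009 to 2158 against 148 to 296 on slide 2, and these spots were left out. Blood or blood-forming kidney tissue in the dissection is argued against as well, since erythroid and kidney genes differed by at most 0.30 in the median. An immune or inflammatory state of the fish of slide 1 may account for it, as a hypothesis: lymphocyte genes, 0 of which are in the microglia or interferon list, were higher by a median of 1.53, though with an adjusted p of 0.0818 with an estimated correlation. Meninges, skin and bone markers were also higher on slide 1 for 30 of 38 genes (median 0.74), and ependyma and choroid plexus markers for 27 of 31 (0.49). Lymphocyte genes therefore cannot tell an immune state of the fish from a difference in the tissue dissected. Clock genes differed between slides as well, with 10 of 44 past the adjusted threshold in both directions, and the time of sampling was not tested. Differences in rearing, infection, dissection day or RNA handling between the samples of the slides were not tested either, and the labels name none.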

How the results depend on the processing

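The tests with slide and position together and with normexp on median signals were chosen after the data were seen; normexp on mean signals, planned, was not run. The adjusted threshold was passed by 0 probes in all settings but 2 with a sample left out (range 0 to 3): without control replicate 3 there were 3 unnamed probes, higher, and without exposed replicate 3 only slc25a10b, lower (adjusted p = 9.15e-04), picked after its values were seen; their low arrays are dim, so no sizes are given. At the looser threshold (1634 probes) there were 738 with normexp, 3205 without a filter on dim probes, 2495 with slide as a block, 2827 with slide and position, 4791 within slide 2, 6956 within slide 1, 3753 with position as a random block, 1003 with unmoderated p, 3296 with array weights and 168 with 1 probe for each of 12676 genes; leaving samples out gave 1467 (without control replicate 1) to 7616 (without exposed replicate 1). Of these, 38.1% were higher without exposed replicate 3, 50.9% without exposed replicate 2 and 75.1% without the filter. Lists called (4) numbered 9 within slide 2, 10 within slide 1, 7 with a gene's probes averaged, 0 with an estimated correlation, 0 with fry, and 2 (without exposed replicate 2) to 16 (without exposed replicate 1) with samples left out, 8 without control replicate 3 and 7 without control replicate 4. Red blood cell markers and neuropeptides were not called within slide 1 (adjusted p = 0.278 and 0.143). Among all 31 lists the direction of the test turned with a call in 7: the interferon list, from -0.83 (without exposed replicate 1, called lower) to 0.24 (without exposed replicate 3, called higher) with samples left out, the microglia list within slide 1 (0.89, higher), the neuronal (-0.27), GABA (-0.26), monoamine (-0.23) and neurogenesis (0.19) lists within slide 1, and the muscle list within slide 2 (0.40) and with samples left out (-0.43 without control replicate 4, not called, to 0.17 without control replicate 2, called higher). Over all named genes the sign turned in 26 of 1354 alternative values; genes chosen for groups that do not overlap could not turn within a slide or with a sample left out. Over all named genes and the 31 lists, 1952 alternative values stayed on their side of the threshold or within their spread, 51 moved further, 44 came past the threshold, 12 fell short of it and 8 reversed. With normexp 3.09% of the kept probes had the sign of the authors' deposited table. The replicate numbers were not treated as pairs: deviations of same-numbered samples correlated at 0.475, -0.303 and 0.193, and no exposed sample correlated best with the control of its own number. With a replicate block 2926 probes passed the looser threshold, 0 the adjusted one, and 9 lists were called. Within slide 1 the lone exposed sample is assumed to vary like the controls. The cause was not tested, except that fewer genes or samples enter the fits with 1 probe per gene, within a slide or with a sample left out. Dim signal limits 33410 probes that were not kept.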

Other observations

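The lists of the 6 further cell types and states, the glucocorticoid list, the tests of the table's direction and the count of splits for adjusted calls were chosen after the results they bear on were seen.

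Beyond the microglia and interferon lists, other immune genes were higher on slide 1 in both groups. Lymphocyte markers (16 measured) were higher by a median of 1.53 on the log2 scale, 12 of 16 genes being higher and 0 shared with the microglia or interferon list (adjusted p = 1.09e-05 with the preset correlation, 0.0818 with an estimated correlation). Interferon-stimulated genes (21, of which 15 are also in the fixed interferon list) were higher by 2.18, and the 6 that are not by 1.12 (adjusted p of all 21 = 4.72e-07, 0.158 with an estimated correlation). Neutrophil markers (11, of which 4 are also in the microglia or interferon list) were higher by 0.85 (adjusted p = 2.89e-04, 0.0818 with an estimated correlation) and genes of reactive glia (16, of which 11 are also in fixed lists) by 0.59 (adjusted p = 1.28e-04, 0.165 with an estimated correlation). Erythroid genes (22, of which 15 are also in the fixed lists, median 0.14, adjusted p = 0.604) and kidney genes (24, median 0.30, adjusted p = 0.229) did not pass. By exposure, erythroid genes were higher by a median of 0.33 (adjusted p = 0.00592 with the preset correlation, 0.615 with an estimated correlation), and the other 5 of these lists did not pass.

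For 11 genes all of their 3 or more probes stood on one side at an unadjusted p under 0.05, 8 higher in exposed samples (fam107b, hsd11b2, klf9, mob2a, pfkfb4b, pik3r3a, smtnl and stk35) and 3 lower (casq2, rgs3a and ttll2); they were picked after their values were seen. Of these, klf9 and hsd11b2 are known to answer glucocorticoids, the stress hormones. Hsd11b2 is the enzyme that inactivates cortisol. Higher glucocorticoid signalling in exposed fish when sampled may be behind the higher level of these genes, as a hypothesis. Of 35 other measured glucocorticoid-responsive genes, 12 of them also in fixed lists, 24 were higher and 11 lower, with a median of 0.14, between the bounds set for and against it, so the test leaves it open. The largest difference among them was 2.13 for fkbp5, whose groups overlapped. Control replicate 1 was the lowest control for fkbp5 (0.77 against 2.59 to 4.53) and klf9 (-3.31 against -1.59 to -1.07), which enlarges both differences. For per1b and angptl4 that sample was the highest control. The list passed with the preset correlation (camera p = 0.00209) and not with an estimated correlation (p = 0.134) or fry (p = 0.228), and its exact permutation p was 0.2. The median was -0.04 within slide 1 and 0.22 within slide 2, and handling before sampling cannot be told apart from exposure here.

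The authors' deposited table has the opposite sign to 10 minus 0 ppb for each of its 1863 probes. Another grouping of the arrays behind it is argued against: 1023 of its p-values lay within 10% of the unmoderated p of the labelled groups, and at most 45 did so for any other split. A ratio turned in the table (0 over 10 ppb) could give the correlation of -0.989, the largest in size over the 35 splits. The next largest was 0.961 in size, and the table was chosen on the labelled groups, so the rank of this correlation says little. An exchange of the 2 group labels as a whole would give the same 1863 opposite signs, and it cannot be told apart from a turned ratio, since nothing in the arrays marks an exposed fish.

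Counting all 35 splits of the 7 samples into 3 and 4, chance cannot be excluded for the looser threshold or the gene lists. For probes past the adjusted threshold the real count was 0, which any split reaches (35 of 35, highest other 12882), so that count decides nothing. For the looser threshold 27 of 35 gave at least the real 1634 (highest other 23398), and for gene lists 34 of 35 gave at least the real 4 (highest other 15). The split that follows the slides gave 12882 probes past the adjusted threshold, 23398 past the looser one and 13 lists, which points to a structure of the samples; the next highest count past the adjusted threshold was 22. With slide as a block, 14 of the 18 splits that keep the slides balanced gave at least the real 2495 (highest other 4649), and 18 splits are too few for a share under 0.05.

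Some probes switched by large steps between arrays in patterns unrelated to the groups. For lyrm2, stmn4, six1b and zgc:171490, different probes of the gene were low in the same arrays. Of 93206 probes 135 fell into sets of arrays separated by at least 16-fold; 0 followed the groups, 7 followed the slides and 54 were low in 1 array, 22 of these in control replicate 4. The probe of slc25a10b, a mitochondrial carrier, was dim and at least 16-fold lower in exposed replicates 1 and 2 than in the other samples (1.32 to 1.47 on the log2 scale), and it was picked after its values were seen.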
